A study of Rattus norvegicus with 3 samples.

How the data were processed

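Rat1 fibroblasts carrying Myc and Rat1 fibroblasts carrying the empty vector were each deprived of serum for 12 h and separated into a soluble, a chromatin-enriched and a crude mitochondrial fraction. Per the labels, vector protein of each fraction was tagged with the light and Myc protein with the heavy ICAT reagent, and the pair was mixed and digested with trypsin. Tagged peptides were separated by cation exchange, purified through biotin, and measured by liquid chromatography with tandem mass spectrometry. Each fraction was measured as 1 mixture, with no swap of the labels, so a difference between the reagents cannot be separated from one between the cells.

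Per the authors' legend, the deposited tables hold 1 line per peptide with its PeptideProphet probability, a protein annotation, the peptide and its linear abundance ratio of Myc over vector. Ratios and their SD at the peptide and protein level were made by the authors with ASAPRatio, from spectra searched against a rat, mouse and human protein database. The versions of these tools, and whether ratios were centred on a common value, are not known. The lowest deposited probability was 0.502. The authors' legend gives the ratios 0, 9999 and -1 as codes for peaks that were not detected in one or both labelled forms, without saying which code means which. Coded proteins, 78 in the soluble, 36 in the chromatin and 6 in the mitochondrial table, were counted and left out of every comparison. The deposited protein ratio, its SD and its number of peptides were read from the text cell that holds them, and were the same on each line of a protein. The number of peptides is there in the mitochondrial table too, although the legend says that it is not. No mass spectra were used here.

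Proteins are named only by short entry names, mostly of Swiss-Prot. The tables do not spell these out, and no table that does was used. The names and functions in the text are therefore a reading of the entry names from general knowledge, and not a look-up. The plan had been to match lists to names as deposited, so this goes beyond the files. Every entry name that could be read with certainty was read, whatever its ratio, after the tables had been opened, and the deposited entry name is printed beside most values. Of 1053 entries 685 were of Swiss-Prot, 620 were read, 28 others took the name of a Swiss-Prot entry with an identical peptide, and 405 stayed unnamed. Of 516 entry names read, 508 were assigned a gene symbol found in the gene table of the rat assembly GRCr8, but only 85 equal a symbol or synonym of that gene there. By their suffix 424 entries were human, 255 mouse and 0 rat. A peptide from rat cells is thus reported under a related species, and human and mouse entries of 1 protein were kept apart. Counts of changed entries and comparisons by identifier do not depend on the names, while lists, makeup and joins by name do.

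A protein was counted as changed when its ratio was at least 1.5 or at most 1 over 1.5 and lay more than 2 deposited errors from 1 on the log scale, with the error as SD over ratio. With 1 mixture per fraction no test across samples is possible, and no p-value is given. For each of 27 lists, defined by patterns on protein names, with at least 3 quantified members in a fraction, the median log2 ratio was placed among 10000 random lists of the same size, matched on the number of peptides. A list stood apart below percentile 2.5 or above 97.5. Between fractions, proteins were joined by identifier and then by name, and differed when the ratios were at least 1.5-fold and more than 2 combined errors apart. The share on the same side of 1 is set beside the share that unrelated ratios would give, from the shares above 1 among the shared proteins, a comparison added after the data were seen, as were the counts between fractions after centring. Shares carry exact (Clopper-Pearson) 95% binomial intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

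The rules, the patterns that define the lists and all but 3 kinds of alternative were chosen before the data were examined. The named proteins are, in each fraction, the 10 highest and 10 lowest changed proteins with a name and at least 2 peptides, every chloride intracellular channel and apoptosis protein, and the highest and lowest member of each list. The 5 largest named differences between each pair of fractions were added. Other members of lists are named as examples, chosen after their values were seen, as are annexin A2 and S100A11 in the mitochondrial fraction. Only 3 soluble, 3 chromatin and 0 mitochondrial proteins met the rule for the lowest. The patterns caught some proteins by part of a word, such as sodium pump chains under nuclear transport and melanotransferrin under serum proteins, and were kept, with an alternative that leaves out 7 of these. Alternatives changed the fold, the error rule, the centring, the number of peptides, the probability, the merging of entries of 1 name, the random lists, the list average and the joining of fractions.

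The steps were tested on simulated data with the number of entries and the errors of each fraction. With 40 of 542 soluble entries set to a 2-fold change, 82.5% were recovered with 9 false calls. With 40 of 364 chromatin entries, 90.0% were recovered with 4 false calls, and with 40 of 201 mitochondrial entries 75.0% with 5. At a 3-fold change 92.5%, 90.0% and 85.0% were recovered. Among 200 random lists of 10 members, 4.50%, 4.00% and 5.00% fell outside the limits in the 3 fractions. The simulated noise came from the deposited errors that the rule itself uses, and the limits set the share of random lists outside them. Few false calls are thus largely fixed in advance, and their rate in the real data is not known. In the real data, 15.4% of soluble and 25% of chromatin pairs of entries of the same protein differed by the rule.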

Results

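Protein abundance was compared between Rat1 fibroblasts, an established rat cell line, that carried Myc and Rat1 fibroblasts that carried the empty vector. Both had been deprived of serum for 12 h, a condition in which cells with high Myc, a transcription factor that drives growth, are prone to apoptosis. The isotope-coded affinity tag (ICAT) labels cysteine, with the light form on vector protein and the heavy form on Myc protein, so that each peptide gives an abundance ratio of Myc over vector. There were 3 samples, each a single labelled mixture: a soluble fraction and a chromatin-enriched fraction with 2.5 mg of protein per label, and a crude mitochondrial fraction with 250 ug per label. No fraction was measured again, so no difference below has a replicate check, and each ± is the deposited SD of a protein ratio within its one mixture.

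The soluble table held 3608 peptide lines for 620 protein entries, of which 542 had a protein ratio. The chromatin table held 2386 lines and 400 entries, 364 of them with a ratio, and the mitochondrial table held 789 lines and 207 entries, 201 with a ratio. A single peptide stood behind 69.0% of the soluble ratios, 71.4% of the chromatin ratios and 66.7% of the mitochondrial ratios. The median SD was 15.4%, 13.2% and 26.1% of the ratio. The median ratio lay above 1 in each fraction, at 1.34 in the soluble, 1.24 in the chromatin and 1.15 in the mitochondrial fraction (log2 0.43, 0.31 and 0.21). Whether the authors centred the ratios is not known, so changes are given both as deposited and relative to these medians. No entry for Myc itself was among the proteins.

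**Figure D1:**
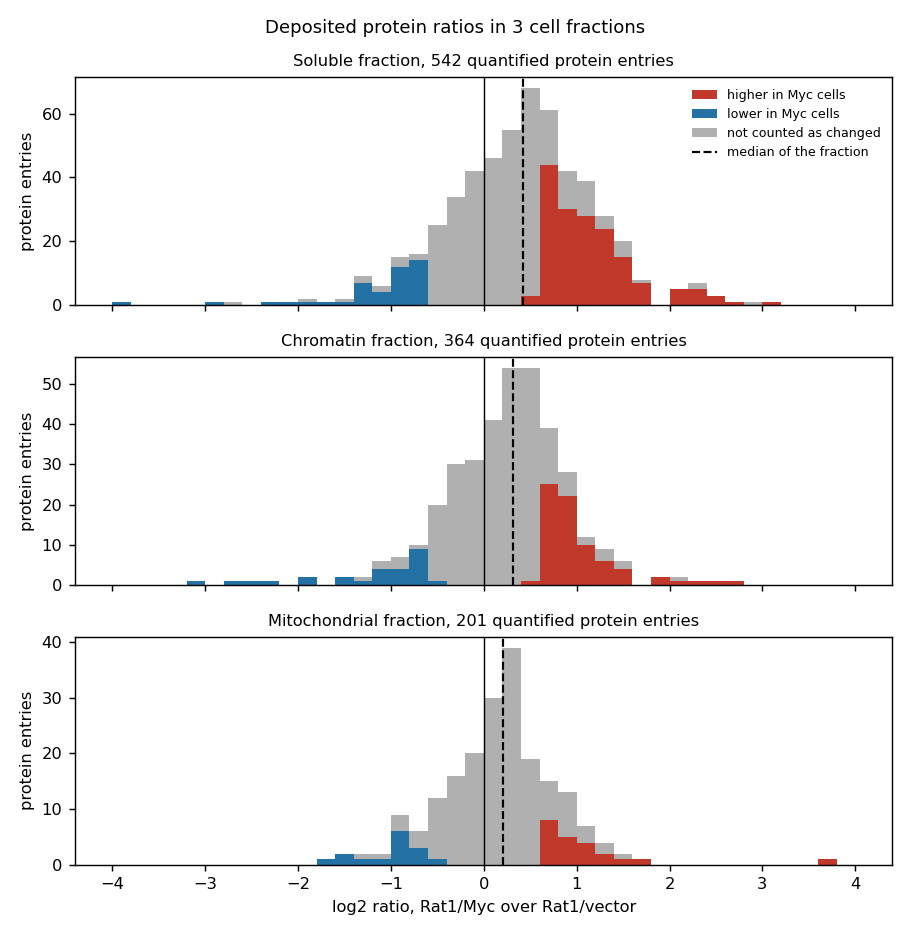
Histograms of the log2 Myc over vector ratio of each protein entry in the 3 fractions, with entries counted as higher in red, lower in blue and the rest in grey. The dashed lines mark the medians of 0.43, 0.31 and 0.21, all to the right of equal abundance at 0.

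In the soluble fraction, the comparison asks which cytosolic and other easily extracted proteins differ in Myc cells without serum. Enzymes of glycolysis were higher as a group by their median (percentile 99.9 of random lists), but not by a mean weighted by the deposited errors (percentile 91.0). Aldolase A, which splits fructose bisphosphate, rose to 3.43 ± 1.07 (entry ALFA_MOUSE), and lactate dehydrogenase A, which turns pyruvate into lactate, rose to 2.61 ± 0.505 (LDHM_MOUSE). Cathepsin D, a lysosomal protease, fell to 0.402 ± 0.047 (CATD_HUMAN), and thrombospondin 1, a secreted matrix glycoprotein, fell to 0.622 ± 0.061 (TSP1_HUMAN). These 4 changes also held relative to the median of the fraction.

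Of the 15 quantified glycolysis entries, 10 were higher, 0 were lower and 12 lay above the median of the fraction. The 10 include both a human and a mouse entry of aldolase A and of the testis form of glyceraldehyde 3-phosphate dehydrogenase, so they are more than the distinct proteins. Their median ratio was 2.19. Alpha enolase (ENOA_HUMAN, 2.98 ± 1.32), phosphoglycerate mutase 1 (PMG1_MOUSE, 2.00 ± 0.532), lactate dehydrogenase B (LDHH_HUMAN, 2.19 ± 0.148) and pyruvate kinase (KPY1_HUMAN, 1.89 ± 0.137) were among the 10, and of these 4 lactate dehydrogenase B alone kept the call relative to the median. The highest was the human entry for that testis form (G3PT_HUMAN, 4.33 ± 1.42). Its mouse entry stood at 2.115 ± 0.196 (G3PT_MOUSE), a pair that differed by the rule, while the entry for the common form stood at 1.15 ± 0.086 (G3P_MOUSE). The lowest was muscle phosphofructokinase, the enzyme that commits sugar to glycolysis, at 0.403 ± 0.195 (K6PF_HUMAN), which passed the rule only relative to the median. With the log2 median of 0.43 subtracted, 5 of the 15 were higher and 1 was lower.

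Proteins of nuclear transport stood at a median of 2.20, percentile 97.8 (81.5 with the error-weighted mean), with 3 of 6 entries higher. The 3 were the import receptor transportin (IMB2_HUMAN, 3.18 ± 1.60), nuclear transport factor 2, which carries Ran into the nucleus (NTF2_HUMAN, 2.95 ± 0.834), and the Ran-binding protein RanBP1 (RANG_HUMAN, 2.43 ± 0.262), of which transportin lost the call relative to the median. One member, a sodium pump chain (A1A1_HUMAN, 0.732 ± 0.178), matched the list by part of a word only, and the list stood at percentile 97.8 or 97.9 with or without it. Cytosolic chaperones had 9 of 21 entries higher and 0 lower at a median of 1.57, which did not set them apart (percentile 83.1). Among the 9 were Hsp90-alpha (HS9A_HUMAN, 2.64 ± 0.587), its partner p23 (P23_HUMAN, 2.50 ± 0.156) and the gamma subunit of the chaperonin that folds actin and tubulin (TCPG_HUMAN, 2.72 ± 0.772).

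Of 9 extracellular matrix and cell surface entries 1 was lower and 1 higher, and their median of 0.842 lay at percentile 0.535, or 23.8 with the error-weighted mean. SPARC, a matrix protein that binds collagen, stood at 0.776 ± 0.063 (SPRC_MOUSE) and 0.842 ± 0.150 (SPRC_HUMAN), and galectin-1, a lectin that binds surface sugars, at 0.754 ± 0.141 (LEG1_HUMAN) and 0.870 ± 0.036 (LEG1_MOUSE), all lower only relative to the median. Of the entries of integrin beta-1, a matrix receptor, the human one was lower relative to the median (ITB1_HUMAN, 0.770 ± 0.150) and the mouse one was not (ITB1_MOUSE, 0.944 ± 0.210). The list's higher entry was lysyl hydroxylase 2, a collagen-modifying enzyme of the endoplasmic reticulum, which rose to 1.84 ± 0.318 (PLO2_MOUSE), though not relative to the median. After centring, 6 of the 9 were lower and 0 higher. Folding proteins of the endoplasmic reticulum had 2 of 4 entries lower, at a median of 0.767 and percentile 1.15. That list lay inside the limits with the error-weighted mean (4.06), with at least 2 peptides (3.97) and against unmatched random lists (3.55). The 2 lower entries were the alpha-1 subunit of the collagen prolyl hydroxylase (P4H1_MOUSE, 0.494 ± 0.103) and protein disulfide isomerase A3 (PDA3_HUMAN, 0.642 ± 0.008), while calreticulin, a calcium-binding chaperone, stood at 1.44 ± 0.134 (CRTC_HUMAN). In the mitochondrial fraction this list was not low. Its median was 1.49 (percentile 90.3), with 0 of 4 entries past the rule and protein disulfide isomerase A3 at 1.70 ± 0.924 (PDA3_MOUSE).

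The highest named soluble proteins with at least 2 peptides also held cyclophilin A, a prolyl isomerase (CYPH_HUMAN, 4.26 ± 1.71), and follistatin-related protein 1, a secreted glycoprotein (FSL1_HUMAN, 3.46 ± 1.69). Hsc70, the constitutive cytosolic chaperone, rose to 2.86 ± 0.810 by its human entry (HS7C_HUMAN), while its mouse entry stood at 1.17 ± 0.263 (HS7C_MOUSE). Also among the 10 highest were S-adenosylmethionine synthetase, which makes the methyl donor of the cell (METK_HUMAN, 2.81 ± 0.730), and mitochondrial aldehyde dehydrogenase (DHAM_HUMAN, 2.74 ± 0.660). Of the 10 highest, 7 remained higher relative to the median of the fraction. Follistatin-related protein 1, transportin and the human entry of aldolase A did not. Thioredoxin, a disulfide reductase, was the highest antioxidant entry at 4.75 ± 1.66 on 1 peptide (THIO_MOUSE). Among translation factors, elongation factor 2 (EF2_HUMAN, 2.71 ± 0.689) and initiation factor 5A (IF5A_HUMAN, 2.43 ± 0.262) rose, and subunit 8 of initiation factor 3 fell to 0.395 ± 0.051 on 1 peptide (IF38_HUMAN). Of 25 mitochondrial matrix entries 11 were higher and 0 lower, among them mitochondrial malate dehydrogenase (MDHM_HUMAN, 2.37 ± 0.474) and the chaperonin Hsp60 (CH60_HUMAN, 2.57 ± 0.308). That list did not stand apart (percentile 87.2), and after centring 9 were higher and 2 lower.

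By the rule, 210 of the 542 soluble entries were changed (38.7%, exact 95% interval 34.6 to 43%), 79.0% of them higher and 44 lower. After centring on the median, 70 were higher and 92 lower, and the higher share was 43.2%. Of the 18 soluble lists tested, 4 stood apart, and the other 14 lay between percentiles 3.66 and 90.4. With the error-weighted mean 0 lists stood apart, but entries with very small deposited errors can dominate that mean. How well it finds a shifted list was not simulated. Only 4 of the 44 lower entries rested on at least 2 peptides.

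**Figure D2:**
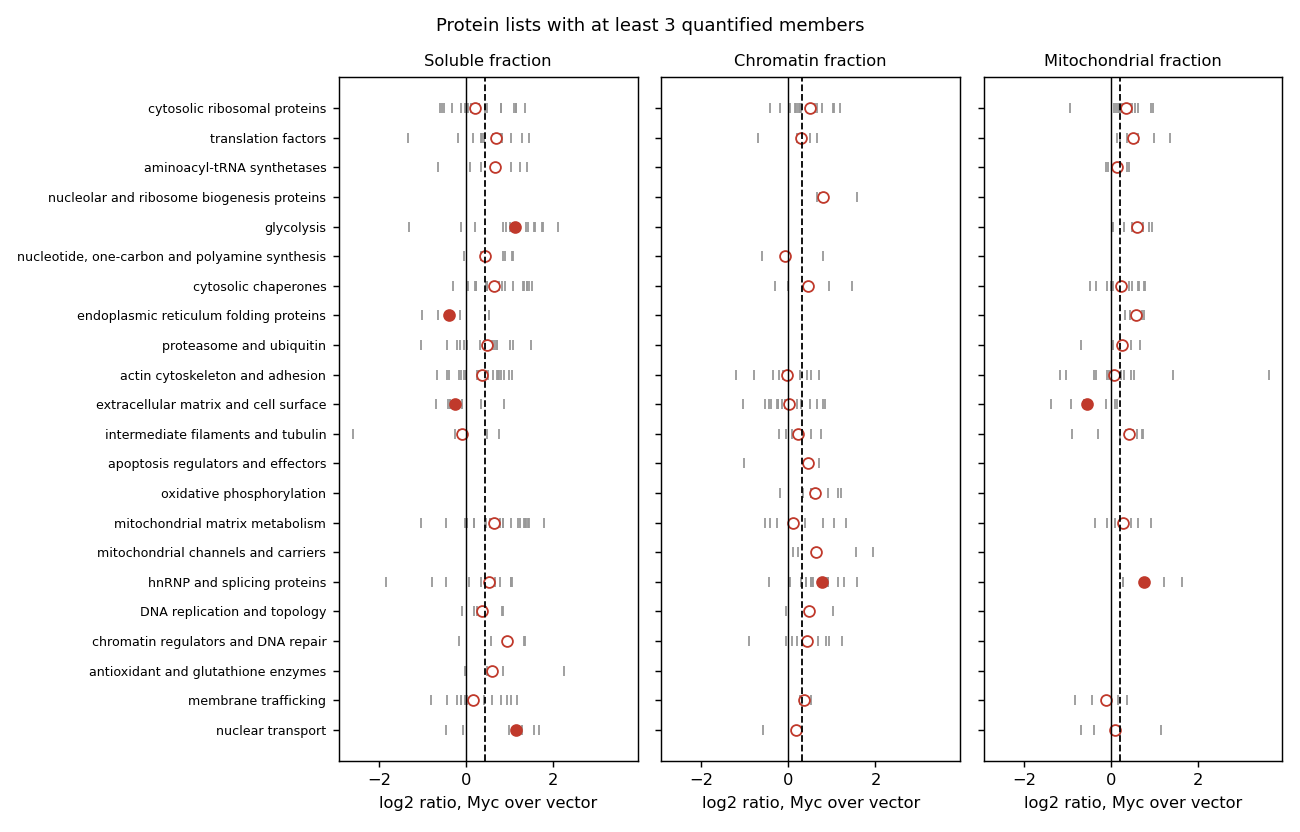
Median log2 Myc over vector ratio (circles) and members (ticks) of each protein list with at least 3 quantified entries, by fraction, with filled circles for lists outside the central 95% of random lists. The dashed line is the median of the fraction, and soluble glycolysis sits at 1.13 against 0.43.

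In the chromatin-enriched fraction, the comparison asks which nuclear and chromatin-bound proteins differ. Proteins that package and splice RNA, in a list that also takes in RNA helicases by name, were higher as a group by their median (percentile 100 of random lists). They did not stand apart by the error-weighted mean (percentile 77.5). Both subunits of the splicing factor U2AF, which marks the end of an intron, rose, to 2.42 ± 0.156 (U2AF_HUMAN, probability 0.941, 1 peptide) and 2.22 ± 0.164 (U2AG_MOUSE). The nucleolar RNA helicase II, which acts in ribosome assembly, rose to 2.99 ± 0.095 on 1 peptide (DD21_MOUSE) and counts in both the splicing and the nucleolar list. Fibronectin, a fibrous matrix protein, fell to 0.484 ± 0.163 by its human entry (FINC_HUMAN), while its mouse entry stood at 0.897 ± 0.106 (FINC_MOUSE).

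Of 23 entries for heterogeneous nuclear ribonucleoproteins (hnRNP) and splicing proteins, 9 were higher, 0 were lower and 20 lay above the median of the fraction. Their median ratio was 1.70, the value of the RNA helicase DEAD-box protein 3 (DDX3_HUMAN, 1.70 ± 1.08), whose mouse entry counts as well (DDX3_MOUSE, 1.33 ± 0.400). Besides U2AF, the 9 held the RNA packaging proteins hnRNP U (ROU_HUMAN, 1.89 ± 0.428, 11 peptides) and hnRNP F (ROF_HUMAN, 1.68 ± 0.161), and the core splicing protein Sm D3 (SMD3_HUMAN, 1.81 ± 0.185). RNA helicase A (DDX9_HUMAN, 1.72 ± 0.242) and the helicase p72 (DD17_HUMAN, 1.72 ± 0.087) were also among them, and none of these 5 kept the call relative to the median. The lowest was a component of the U5 splicing particle, at 0.739 ± 0.017 (U5S1_HUMAN, probability 0.783), which was lower only relative to the median. After centring, 4 of the 23 were higher and 1 was lower. Of 4 nucleolar entries 3 were higher, at a median of 1.72 and percentile 95.3, including fibrillarin, which methylates ribosomal RNA (FBRL_HUMAN, 1.78 ± 0.298), whose call did not hold relative to the median.

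Of 8 chromatin regulators and repair proteins 4 were higher and 1 lower, at percentile 70.8. Retinoblastoma-binding protein 7, a histone-binding subunit of deacetylase complexes, was the highest (RBB7_HUMAN, 2.34 ± 0.367), and the abundant DNA-bending protein HMG1 (HMG1_HUMAN, 1.92 ± 0.337) also rose. The remodelling enzyme CHD4 rose as well (CHD4_HUMAN, 1.59 ± 0.142), but not relative to the median. The BRG1-associated factor of 53 kDa fell to 0.536 ± 0.053 (B53A_HUMAN, probability 0.897, 1 peptide). DNA topoisomerase II alpha, which untangles replicated DNA, rose to 2.05 ± 0.105 (TP2A_HUMAN, probability 0.757, 1 peptide). The histone entries stood at 0.957 ± 0.321 (H32_BOVIN) and 1.29 ± 0.119 (H31_HUMAN). Ribosomal protein P0 (RLA0_HUMAN, 2.26 ± 0.305), a small subunit of respiratory complex III (UCRH_MOUSE, 2.19 ± 0.432, with the human entry UCRH_HUMAN at 1.42 ± 0.238) and the transcription factor NFI-C (NFIC_HUMAN, 2.01 ± 0.283) were also among the 10 highest named proteins. Of these 10, only these 3 and retinoblastoma-binding protein 7 remained higher relative to the median of the fraction.

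Gamma actin fell to 0.581 ± 0.060 (ACTG_HUMAN) while beta actin, a nearly identical filament protein, rose to 1.62 ± 0.182 (ACTB_HUMAN), though not relative to the median. For ribosome-binding protein 1 of the endoplasmic reticulum the entries disagreed, with the human entry lower at 0.643 ± 0.068 (RRB1_HUMAN) and the mouse entry at 1.68 ± 0.554 (RRB1_MOUSE). Of 19 matrix and surface entries 1 was lower and 2 were higher, at a median of 1.00 and percentile 3.83, and relative to the median of the fraction 2 were lower and 0 higher. Among apoptosis proteins, the entry for BAK-2, a relative of the cell death protein BAK, fell to 0.491 ± 0.015 on 1 peptide (BAK2_HUMAN), identified with a probability of only 0.832. Poly(ADP-ribose) polymerase 1, a DNA damage enzyme cleaved in apoptosis, rose to 1.62 ± 0.128 on 1 peptide (PPOL_HUMAN), a change that did not hold relative to the median of the fraction. The entry for p53-binding protein 1, a DNA repair factor that matched the list by its name only, stood at 1.37 ± 1.16 (P531_HUMAN, probability 0.722).

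By the rule, 101 of the 364 chromatin entries were changed (27.7%, interval 23.2 to 32.7%), 74 higher and 27 lower, so that 73.3% were higher. With the log2 median of 0.31 subtracted, 34 were higher and 48 lower, a higher share of 41.5%. Of 17 lists tested 1 stood apart, and the other 16 lay between percentiles 3.83 and 95.3. With the error-weighted mean 0 of them did. Only 4 of the 27 lower entries rested on at least 2 peptides.

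In the crude mitochondrial fraction, the comparison asks which proteins at or near mitochondria differ. Chloride intracellular channel 4, a channel protein found in mitochondria and other membranes, rose to 2.56 ± 0.544 on 2 peptides (AF102578_1). Annexin A2 and S100A11, which are calcium-binding proteins, fell to 0.335 ± 0.069 (ANX2_MOUSE) and 0.316 ± 0.146 (S111_MOUSE), each on 1 peptide. Each of these 3 changes also held relative to the median of the fraction. Matrix and surface proteins were lower as a group by their median (percentile 0.760), but not by the error-weighted mean (percentile 12.3), and with at least 2 peptides the list was too small to test.

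For chloride intracellular channel 4, the 2 peptides differed. One gave 4 measurements between 1.97 and 2.99, and the other gave 1 of 1.38 ± 0.392. The soluble fraction held only that other peptide, with measurements of 0.654 ± 0.141 and 1.54 ± 0.211 and a protein ratio of 0.993 ± 0.564 (CLI4_MOUSE). The soluble and mitochondrial protein ratios lay 1.56 combined errors apart, short of the 2 that the rule asks for. The chromatin table held 0 quantified entries for a chloride intracellular channel.

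**Figure D3:**
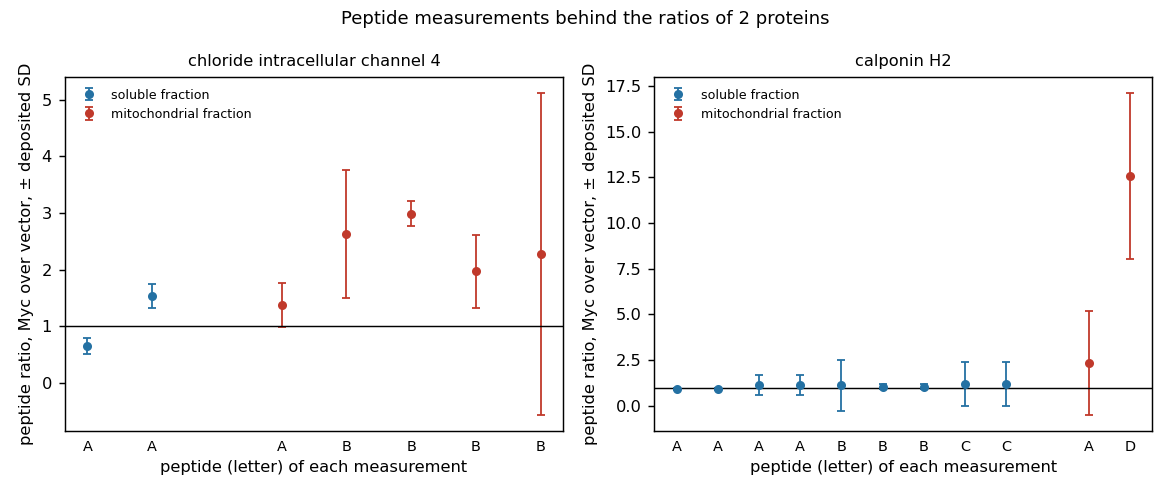
Peptide ratios of Myc over vector with the deposited SD for chloride intracellular channel 4 (left) and calponin H2 (right), in the soluble (blue) and mitochondrial (red) fractions, where letters mark distinct peptides. In the mitochondrial fraction 1 of the 2 peptides of each protein carries the high ratio, at up to 2.99 and 12.6.

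Of 8 matrix and surface entries in the mitochondrial fraction 4 were lower and 0 higher, at a median of 0.679. The 4 lower entries were SPARC (SPRC_MOUSE, 0.384 ± 0.149), galectin-1 (LEG1_MOUSE, 0.533 ± 0.132), laminin gamma-1, a chain of the basement membrane (LMG1_MOUSE, 0.651 ± 0.057), and integrin beta-1 (ITB1_MOUSE, 0.660 ± 0.046). Each of the 4 rested on 1 peptide. Fibronectin stood at 0.698 ± 0.175 (FINC_MOUSE), and 0 of the 8 lay above the median of the fraction.

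The highest named protein was calponin H2, an actin-binding protein, at 12.4 ± 2.43 (CLP2_MOUSE). That ratio rested on a peptide identified with a probability of 0.570, and the other peptide gave 2.36 ± 2.84. Phosphoglycerate dehydrogenase, the first enzyme of serine synthesis, rose to 3.00 ± 0.365 (SERA_MOUSE), and cyclophilin A to 2.04 ± 0.211 (CYPH_MOUSE). The start-site factor SUI1 (SUI1_MOUSE, 1.97 ± 0.492), ribosomal protein L12 (RL12_MOUSE, 1.95 ± 0.017), Hsp90-alpha (HS9A_MOUSE, 1.73 ± 0.100) and elongation factor 2 (EF2_MOUSE, 1.54 ± 0.238) also rose. Of the 10 highest, 7 remained higher relative to the median of the fraction, and elongation factor 2 was among the 3 that did not. The outer membrane channel VDAC1 rose to 1.96 ± 0.495 (POR1_MOUSE). Of 6 mitochondrial matrix entries 1 was higher and 0 lower (percentile 68.8), and after centring 0 were either. They ran from serine hydroxymethyltransferase (AK012355_1, 0.770 ± 0.399), aconitase (BC004645_1, 0.946 ± 0.937) and malate dehydrogenase (MDHM_MOUSE, 1.07 ± 0.795) to dihydrolipoyl dehydrogenase, the one that rose (DLDH_MOUSE, 1.54 ± 0.231), and Hsp60 (CH60_MOUSE, 1.88 ± 0.780). Cathepsin B, a lysosomal protease, stood at 1.07 ± 0.036 here and 0.976 ± 0.256 in the soluble fraction (CATB_MOUSE).

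The hnRNP and splicing list had 4 entries with a median of 1.69, at percentile 98.1 (97.3 against unmatched random lists and 75.0 with the error-weighted mean), and 1 of them rose, the RNA export helicase UAP56 (AC007080_3, 3.09 ± 1.23). Glycolysis entries stood at a median of 1.52, percentile 97.1, with 0 of 6 past the rule. By the rule, 37 of the 201 mitochondrial entries were changed (18.4%, interval 13.3 to 24.5%), 22 higher and 15 lower, so that 59.5% were higher. With the log2 median of 0.21 subtracted, 14 were higher and 23 lower, a higher share of 37.8%. Of 14 lists tested 2 stood apart, and the other 12 lay between percentiles 15.3 and 97.1. With the error-weighted mean 0 of the 14 did. Of the 15 lower entries, 0 rested on at least 2 peptides.

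The make-up of the tables shows how far each fraction held the proteins its name implies. The chromatin table held the largest share of nuclear RNA-binding proteins, with 23 hnRNP and splicing entries among 364 (6.32%, exact 95% interval 4.05 to 9.33%), against 11 of 542 in the soluble (2.03%, 1.02 to 3.60%) and 4 of 201 in the mitochondrial table (1.99%, 0.545 to 5.02%), whose interval overlaps that of chromatin. Histones, which hold few cysteines, gave 2 entries in chromatin and 0 elsewhere. Proteins of the mitochondrial membranes lay mostly in the chromatin table. Oxidative phosphorylation gave 8 chromatin entries (2.20%, 0.954 to 4.28%) and 1 mitochondrial entry (0.498%, 0.0126 to 2.74%), and mitochondrial channels and carriers gave 7 (1.92%, 0.777 to 3.92%) and 1. For each of these 2 lists the intervals overlap. The chromatin entries of both lists include human and mouse entries of 1 protein (UCRH, UCR2, POR1 and POR2), counted apart.

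Among these, subunit 3 of respiratory complex I rose in the chromatin fraction to 2.30 ± 0.156 (NU3M_MOUSE, 1 peptide), and the outer membrane channel VDAC2 to 3.84 ± 0.980 (POR2_MOUSE, 1 peptide) and 1.503 ± 0.223 (POR2_HUMAN), the last of which did not hold relative to the median. The complex I subunit was identified with a probability of 0.543. Enzymes of the mitochondrial matrix were spread over the soluble table (25 entries, 4.61%), the chromatin table (10, 2.75%) and the mitochondrial table (6, 2.99%). Cytosolic ribosomal proteins made up 9.95% of the mitochondrial table (20, 6.18 to 14.9%), 5.77% of the chromatin table (3.61 to 8.68%) and 4.24% of the soluble table (2.71 to 6.30%). Actin cytoskeleton proteins made up 7.46% (15, 4.24 to 12.0%), 3.57% (1.92 to 6.03%) and 4.06% (2.56 to 6.08%), and cytosolic chaperones 6.97% (14, 3.86 to 11.4%), 1.10% (0.3 to 2.79%) and 3.87% (2.41 to 5.86%). Of these mitochondrial shares, the intervals overlap those of the other tables except for chaperones against chromatin. Keratins gave 0 entries. The only serum list match was melanotransferrin, a membrane protein, which fell to 0.535 ± 0.012 in the soluble fraction (TRFM_MOUSE, probability 0.679). These intervals cover counting error only, and entries without a readable name count in the totals but in no list.

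Comparing fractions asks whether a protein moved alike in different parts of the cell. Between the soluble and chromatin fractions, Hsp60 stood at 2.57 ± 0.308 and 0.750 ± 0.189 (CH60_HUMAN), and cyclophilin A at 2.43 ± 0.083 and 0.801 ± 0.208 (CYPH_MOUSE). Hsc70 stood at 2.86 ± 0.810 and 0.802 ± 0.078 by its human entry (HS7C_HUMAN), a contrast that rests on the entry joined, since the mouse entry in the soluble fraction stood at 1.17 ± 0.263 (HS7C_MOUSE). The RNA-binding protein p54nrb showed the same order, at 2.40 ± 0.891 and 0.823 ± 0.207 (NR54_HUMAN). Sm D3 showed the opposite order, at 0.278 ± 0.254 and 1.81 ± 0.185 (SMD3_HUMAN). Of 96 shared proteins 20 differed by the rule, 12 with the higher ratio in the soluble fraction and 8 in chromatin, a split that turned to 9 and 13 after centring on the medians. The 5 differences named held after centring. On the ratios as deposited 58 of the 96 lay on the same side of 1 (60.4%, 49.9 to 70.3%, where unrelated ratios would give 60.5%). Across these proteins, which are not independent replicates, Pearson's r of the log2 ratios was 0.19 and Spearman's rho 0.21.

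Between the soluble and mitochondrial fractions, the largest differences among named proteins that differed by the rule were calponin H2 (1.01 ± 0.137, CLP2_HUMAN, and 12.4 ± 2.43, CLP2_MOUSE) and aldolase A (3.43 ± 1.07 and 1.03 ± 0.249, ALFA_MOUSE). For calponin H2 the contrast rests on different peptides, since the one with the high ratio was coded in the soluble fraction and the only one measured in both gave 2.36 ± 2.84 in the mitochondrial fraction. The mouse entry of calponin H2 was coded in the soluble fraction. The small GTPase CDC42, which shapes the actin skeleton, followed by its brain isoform (1.54 ± 0.404 and 0.518 ± 0.005, G25B_HUMAN), with the placental isoform closer together (1.29 ± 0.059 and 0.771 ± 0.096, G25P_HUMAN). Next were the chaperonin gamma subunit (2.72 ± 0.772 and 1.01 ± 0.375) and p23 (2.50 ± 0.156 and 0.935 ± 0.402). The last 2 did not hold after centring. Of 127 shared proteins 20 differed, 16 with the higher ratio in the soluble and 4 in the mitochondrial fraction, but after centring 10 of the 16 were lost and the split turned to 6 and 9. On the ratios as deposited 81 of the 127 lay on the same side of 1 (63.8%, 54.8 to 72.1%, against 63.0% if unrelated). Pearson's r across proteins was 0.12 and Spearman's rho 0.19. The value depends on how proteins were paired, since r was 0.47 over the 54 joined by the same identifier and -0.06 over the 73 joined by name.

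Between the chromatin and mitochondrial fractions, annexin A2 stood at 1.06 ± 0.124 and 0.335 ± 0.069, and the small GTPase RhoA at 1.27 ± 0.114 and 0.691 ± 0.198. Cyclophilin A stood at 0.801 ± 0.208 and 2.04 ± 0.211, and the chaperonin alpha subunit at 2.74 ± 0.411 and 1.33 ± 0.125 (TCP1_MOUSE). Ribosome-binding protein 1 stood at 0.643 ± 0.068 by its human entry in chromatin (RRB1_HUMAN) and at 1.82 ± 0.430 in the mitochondrial fraction (AK019964_1). Its mouse entry in chromatin, at 1.68 ± 0.554 (RRB1_MOUSE), lay near the mitochondrial value, so the contrast rests on the entry joined. Of these 5 differences, that of RhoA did not hold after centring. Of 67 shared proteins 6 differed, 4 with the higher ratio in chromatin and 2 in the mitochondrial fraction, or 3 and 4 after centring, and 43 lay on the same side of 1 (64.2%, 51.5 to 75.5%, against 57.5% if unrelated). Pearson's r across proteins was 0.33 and Spearman's rho 0.36. There were 48 proteins in all 3 fractions.

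**Figure D4:**
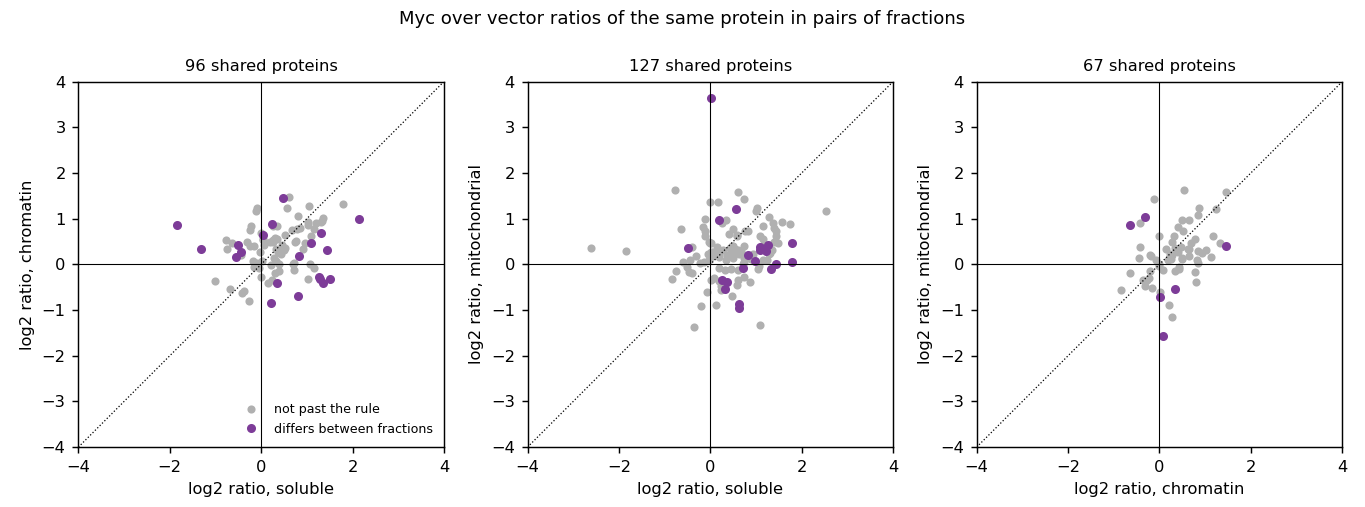
Log2 Myc over vector ratio of each shared protein in 1 fraction against another, with proteins that differ by the rule in purple and the line of equal ratios dotted. The 20, 20 and 6 differing proteins lie among 96, 127 and 67 shared ones.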

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

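Of the tests given here, those of mixing and of the soluble ratio for chloride intracellular channel 4, all 3 on mitochondrial membrane proteins and the share of proteins beyond deposited error were chosen after the result was seen, and the test of peptide probability was added after the others.

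In 3 cases a protein was counted as higher in 1 fraction and lower in another, each 1 mixture, and the difference was not tested across cultures. A subunit of translation initiation factor 2, which brings the first tRNA to the ribosome, stood at 1.74 ± 0.3 in the soluble and 0.617 ± 0.086 in the chromatin fraction (IF2G_HUMAN, 2.82-fold apart). The unnamed entry AK013776_1 stood at 1.56 ± 0.155 in the soluble and 0.551 ± 0.030 in the mitochondrial fraction (2.82-fold). Ribosome-binding protein 1 stood at 0.643 ± 0.068 in the chromatin (RRB1_HUMAN) and 1.82 ± 0.430 in the mitochondrial fraction (AK019964_1, 2.83-fold), while its mouse entry in chromatin stood at 1.68 ± 0.554 (RRB1_MOUSE), near the mitochondrial value. After centring on the median of each fraction the higher call was lost in all 3 cases and the lower call was kept.

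The ratios of 1 protein in the soluble and mitochondrial fractions were only weakly related across 127 proteins (r 0.12), but r was 0.47 over the 54 joined by the same identifier and -0.06 over the 73 joined by name, so the pattern depends on the join. Deposited error cannot be told apart from a difference between fractions, although 18.1% of proteins lay more than 2 combined errors apart (23, interval 11.8 to 25.9%). Normal errors of known size without an offset would allow 5%, but the deposited error covers only the spread within each single mixture. The ratios were also used here as deposited, without centring on the fraction medians of log2 0.43 and 0.21. The test of combined errors replaced one written before its result and dropped after it was seen, which decides nothing either, since it rests on the same deposited errors. In it, 1000 correlations simulated over all 127 proteins with deposited error alone had a median of 0.39 (central 95% 0.20 to 0.58), a range without the 0.12. No range was simulated for the 54 joined by identifier, so their 0.47 cannot be set against it. Leaving out the 8 proteins identified below 0.95 in either fraction did not raise r, which was 0.11 over the other 119 (-0.08 to 0.28, below the bound of 0.288). The test could hardly pass that bound, since even the most favourable 8 found gave only 0.34. A protein's probability is also the highest of its peptides, so calponin H2 stayed in. Proteins of low probability thus stay open, as do peptides of low probability, at 0.16 over 60 proteins (-0.09 to 0.40). Spread between entries of 1 protein cannot be told apart from a difference between fractions, since the median absolute log2 difference was 0.65 between fractions and 0.54 within the soluble one, a gap of 0.11 with an interval of -0.12 to 0.39, and wrong joins by name and a true difference between fractions stay open as untested.

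Chloride intracellular channel 4 was higher in the mitochondrial fraction (2.56 ± 0.544). Unequal mixing of the labelled protein as the whole cause is argued against by its ratio to the median of the fraction, 2.22, which lies 3.75 errors from 1. A single deviating peptide stays open as a candidate explanation, since the lowest of 5 measurements was 1.38, from a different peptide than the other 4, the highest of which was 2.99. The same change in the soluble fraction cannot be told apart from one in the mitochondrial fraction alone, at 1.56 combined errors between the ratios, because the soluble ratio rests on 1 peptide with a wide error. An effect of Myc on the protein, the difference the design names, stays open as untested, since there is 1 culture pair.

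Mitochondrial membrane proteins lay mostly in the chromatin table, with 15 entries against 2 in the mitochondrial table. The chromatin entries include both a human and a mouse entry for VDAC1, VDAC2 and complex III subunits (UCRH, UCR2). They are thus more than the distinct proteins, here and in the tests below, while the mitochondrial table held no such pair of membrane entries. Exchanged labels are argued against by the nuclear lists, which took 2.49% of the mitochondrial table (5, interval 0.813 to 5.71%) and 10.7% of the chromatin table (39, 7.73 to 14.4%). The smaller size of the mitochondrial table cannot be told apart from a true lack, although 0.0846% of draws of that size from the chromatin table held as few. Such draws leave out the counting error of the chromatin table and treat human and mouse entries of 1 protein as separate. The intervals of the shares overlap (0.121 to 3.55% and 2.32 to 6.71%). Entries hidden among the unnamed ones cannot be told apart from absent ones, since 32 mitochondrial entries are unnamed, 7 more membrane entries would be needed, and 0 of the 32 share a peptide with the named ones. How mitochondria were divided between the fractions was not tested, and no biological explanation was tested.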

How the results depend on the processing

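Tests chosen only after the data were seen are those with named entries only, with names found in the gene table and without part-word matches. Each result was recomputed with 1 choice changed at a time, and unless said otherwise the cause of a move was not tested. Of the values that answer a comparison, 117 stayed, 47 moved, 10 lost their place outside the limits and 1 reversed. A count stayed when it lay within 1.5-fold of the main count, and a share or r when it lay inside its interval. The 117 do not measure robustness, since some choices cannot move some values, such as centring for list percentiles and r. Of the other values, 287 stayed, 26 moved and 1, mitochondrial glycolysis with merged names, newly stood apart.

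Counts of higher and lower entries follow the size of the rule by construction. With a fold of 2 they were 89 and 18 in the soluble, 26 and 13 in the chromatin and 9 and 5 in the mitochondrial fraction. With at least 2 peptides they were 56 and 4, 21 and 4, and 12 and 0, and with named entries only 106 and 17 in the soluble and 45 and 13 in the chromatin fraction. At a probability of 0.95 lower entries were 25 in the soluble and 12 in the chromatin fraction. Mitochondrial counts were 43 and 23 without the error rule, and 9 were lower at more than 3 errors. Centring turned the excess of higher entries into an excess of lower ones in each fraction, at 70 and 92, 34 and 48, and 14 and 23. By construction it leaves list percentiles and r as they were.

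With the error-weighted mean 0 lists stood apart in the soluble, 0 in the chromatin and 0 in the mitochondrial fraction. That mean weights each entry by the inverse square of its SD over ratio. An entry with a very small SD, such as soluble protein disulfide isomerase A3 (PDA3_HUMAN, 0.642 ± 0.008), can thus carry most of it. The power of that mean to find a shifted list was not simulated, so it cannot show that a shift is absent. In the soluble fraction the percentiles with that mean were 91.0 for glycolysis, 4.06 for endoplasmic reticulum folding, 23.8 for matrix and surface and 81.5 for nuclear transport. For hnRNP and splicing in chromatin it was 77.5. In the mitochondrial fraction they were 12.3 for extracellular matrix and cell surface and 75.0 for hnRNP and splicing. With only names found in the gene table, 0 stood apart in each fraction, but only 4, 2 and 0 lists could be tested. With at least 2 peptides endoplasmic reticulum folding moved to 3.97 and 0 mitochondrial lists stood apart. With unmatched random lists it moved to 3.55 and mitochondrial hnRNP to 97.3, which left 1 mitochondrial list. Without part-word matches 4, 1 and 2 lists stood apart.

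Between the soluble and mitochondrial fractions r was 0.47 for proteins joined by identifier only and reversed to -0.036 with at least 2 peptides in both. The latter set still held calponin H2 (1.01 and 12.4), and its r without that protein was not computed. With at least 2 peptides in both, the share on the same side of 1 rose to 73.7%, and to 76.2% between chromatin and mitochondrial. What unrelated ratios would give was not computed for these smaller sets. The share differing was 9.68% between soluble and chromatin with at least 2 peptides in both. At more than 1 combined error it was 38.5% there, 42.5% between soluble and mitochondrial and 23.9% between chromatin and mitochondrial. With at least 2 peptides, matrix enzymes were 8.33% of the soluble and channels 4.81% of the chromatin table, while mitochondrial oxidative phosphorylation, channels and hnRNP gave 0%, 0% and 0%.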

Other observations

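No test in this part was planned, and the items in it were chosen after their values were seen.

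Entries of 1 protein under human and mouse names in the same fraction can be set side by side. In the soluble fraction, Hsp60 stood at 2.57 ± 0.308 (CH60_HUMAN) and 2.60 ± 0.179 (CH60_MOUSE) and aldolase A at 2.94 ± 1.16 (ALFA_HUMAN) and 3.43 ± 1.07 (ALFA_MOUSE). Hsc70 stood further apart, at 2.86 ± 0.810 (HS7C_HUMAN) and 1.17 ± 0.263 (HS7C_MOUSE). In chromatin, fibronectin stood at 0.484 ± 0.163 (FINC_HUMAN) and 0.897 ± 0.106 (FINC_MOUSE). Across 26 such pairs in the soluble fraction r was 0.60 and 4 pairs differed by the rule. Across 12 in chromatin r was 0.44 and 3 differed. In neither fraction were 2 entries of 1 protein called in opposite directions.

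Entries identified with a probability under 0.95 were counted as changed in 39 of 72 cases in the soluble fraction (54.2%, exact interval 42.0 to 66.0%) against 36.4% (32 to 40.9%) of the rest. In chromatin the shares were 40.6% (28.9 to 53.1%) and 24.7% (19.9 to 30.1%), and in the mitochondrial fraction 30% (3 of 10, 6.67 to 65.2%) and 17.8% (12.7 to 24%), and in both the intervals overlap. The differences were not tested. Of the soluble entries under 0.95, 20 were higher and 19 lower. These intervals cover counting error only.

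Coded proteins, without a usable ratio, include spermidine synthase in the soluble fraction (SPEE) and cathepsin D in the mitochondrial fraction (CATD_MOUSE).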
